A study of Mus musculus with 12 samples.

How the data were processed

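Total RNA was sequenced from 12 cultures, 3 clones of mouse embryonic stem cells with a cRAF-ERT2 construct at 4 times (untreated and 1, 2 and 4 h of 250 nM 4OHT). The titles and the series design give these times and the design this dose for each, while the treatment protocol of the samples names only 0 h and 2 h. Per the labels' protocols, cells were grown in serum medium with LIF and 2 µM Chir99021, were moved 24 h before treatment to serum medium with LIF and 250 nM PD173074, and received 5 mM ethynyl uridine for 15 min before RNA isolation. Ribosomal RNA was depleted and libraries were made with the NEB Next Ultra 2 kit, per the labels' protocols. No enrichment of the uridine-labelled RNA is described there for these samples.

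The authors deposited 1 table of raw read counts per gene symbol, with 1 column per library. The submitters' processing notes name STAR, featureCounts and DESeq and the mm10 genome build; versions, the gene annotation, the strand setting and the treatment of multiply mapped reads are not given in the sources used here. Without the strand setting, counts of a gene and of a gene overlapping it cannot be separated, so named genes with overlapping exons are uncertain. Besides those given as overlapping elsewhere, these are Pou5f1, Tbx3, Gata6, Cyp51, Sox1, Sox8, Spp1, Tfcp2l1, Lrig1, Cdk2, 1600014C10Rik, Gphn, Tmtc2, Rsph3a, Col6a6, Sugct, Fgfr2, Vwa3a and Il31ra. The table held 25897 symbols, of which 6472 had 0 counts in all libraries and 13 mitochondrial genes had 0 counts. Against GENCODE M21 (GRCm38), 25532 symbols matched 1 gene, 37 more than 1 and 328 none, and 24 symbols had the form of a calendar date, as spreadsheet programs produce, and were not named. Coordinates are from GENCODE M21, counted from 1.

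Groups and clones were taken from the sample labels, and the deposited columns were matched to samples by time and clone letter. Libraries differed by more than sampling noise (chi-square per degree of freedom 19.2 to 107 over the 12 pairs within groups and 15.8 to 266 over all 66 pairs), so no library is a copy of another, and all 12 were kept. Total counts of 24213641 to 31435301 per library put 1 count at 0.0318 to 0.0413 CPM before scaling.

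Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 14185 tested and 11712 not tested. Counts were scaled by TMM, and a quasi-likelihood model with 1 term per group was fitted to all 12 libraries (edgeR 4.0.16, limma 3.58.1, R 4.3.3; 8 residual degrees of freedom, biological coefficient of variation 0.163). Each pair of times was tested 2-sided with Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05, and an F test took the 3 treated times together. Log2 changes are given ± SE. This SE is the absolute log2 change divided by the square root of the model's F statistic, and is approximate. CPM is given as mean ± SD of 3 clones, with a prior count of 2 for log2 CPM. For genes with 0 counts in a group a bound was computed against 3 counts over the group, and for genes with 1 to 3 counts the ratio with a 95% counting interval.

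The clone letter is shared by the libraries of 1 clone at all times, so it pairs libraries across groups. Deviations from the group means correlated in 18 of 18 same-clone pairs (r 0.184 to 0.684), while pairs of different clones had r from −0.568 to −0.024, and 12 of 12 libraries correlated best with their own clone. The fit with clone as a block had 6 residual degrees of freedom and a coefficient of variation of 0.0924, and its values stand beside results that it changes.

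There were 24 fixed gene lists, from textbook knowledge: immediate-early genes, ERK feedback, ETS-type ERK targets, naive and general pluripotency, formative epiblast, primitive endoderm, primitive streak and mesoderm, trophoblast, neural, feeder fibroblast, Wnt targets, LIF and STAT3 targets, two-cell-like, SRF and cytoskeleton, ligands and receptors, ribosome biogenesis, cell cycle, p53 targets, integrated stress, heat shock, sterol synthesis, oestrogen response and RNA quality. Each of the 23 with at least 3 tested members went through camera with a preset correlation of 0.01, adjusted over the lists of 1 time, and again with an estimated correlation. The estimate came from the fit without the clone block, so differences between clones enter it. No estimate was made with the block. Camera compares a list with other genes, while fry tests whether its members move, on balance, one way and compares them with no other genes. Some members are in more than 1 list, such as Cdx2, Klf4, Gbx2 and Fgf4.

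Named were, per comparison with untreated cells, the 10 largest rises and 10 largest falls among genes past the threshold that moved the same way in all 3 clones and averaged at least 1 CPM over the 12 libraries. The rule left out predicted genes with symbols starting in Gm or ending in Rik and pseudogenes. Also named were 5 rises and 5 falls between times, up to 4 members of each list by smallest p, and a panel of 13 genes (Egr1, Fos, Dusp6, Spry4, Etv4, Nanog, Klf4, Esrrb, Tbx3, Pou5f1, Sox2, Gata6 and Gata4), with Esr1 as a check of the construct. Some results under this rule are not reported here. Further list members past the threshold, Nlrp12, the genes of opposite direction and the genes varying with Lars2 were named after their values were seen, and the alternatives were read for genes under the rule.

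Groups, tests, lists, the naming rule and the alternatives were set before the data were examined. The alternatives were RLE size factors, no or a stricter low-count filter (1 CPM in 6 libraries), DESeq2 1.42.0, limma-voom, clone as a block, a test against a 1.5-fold change, a fit of the 2 groups compared, fry or an estimated correlation for lists, and leaving out each library, or for lists each clone. Chosen after seeing the data were leaving out all libraries of a clone for gene counts, leaving out 15 genes that vary with Lars2, and DESeq2 with clone as a block. The 15 genes had a correlation with Lars2 of at least 0.9, over the 12 libraries and within groups, and their transcripts were compared with mitochondrial 16S ribosomal RNA by blastn 2.17.0 (E-value limit 1e-05).

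The model was tested on simulated data made from the real means and library sizes, with 200 genes changed in the 4 h against untreated comparison. The changed genes were drawn from those averaging at least 1 CPM, and the simulated clone effect was the same at each time. Data with no clone effect took the dispersions of the fit without the block, which already hold the clone differences as noise. Data with a clone effect took those of the blocked fit. The shares of these settings therefore do not show what a clone effect costs. With no clone effect (14048 genes run), it recovered 37.3% of 1.5-fold, 77.6% of 2-fold and 97.0% of 4-fold changes, and 4 of 145 called genes were unchanged. With a clone effect of the real size (14097 genes run) the recovered shares were 41.8%, 71.6% and 97.0%, with 0 of 140 called genes unchanged. The fit with clone as a block then recovered 76.1%, 91.0% and 100% and 15 of 193 called genes were unchanged.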

Results

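RNA was sequenced from E14tg2a cells, a mouse embryonic stem cell line of the 129SV background, that carry a cRAF-ERT2 construct. In this fusion a kinase is joined to a hormone-binding domain of the oestrogen receptor, so that 4-hydroxytamoxifen (4OHT) switches on the kinase and with it the ERK pathway. Clones a, b and c were each sampled untreated and after 1, 2 and 4 h of 250 nM 4OHT, which gave 12 libraries in 4 groups of 3 clones. Cells were grown in serum medium with LIF and 2 µM Chir99021. They were moved 24 h before treatment to serum medium with LIF and 250 nM PD173074, an inhibitor of FGF receptors. Ethynyl uridine was added 15 min before harvest, and ribosomal RNA was depleted from total RNA. No vehicle-treated group is among these samples, so time in 4OHT and any effect of the carrier or of the ligand itself were not separated.

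The deposited table gave read counts for 25897 gene symbols. Total counts per library were 27190000 ± 2980000 in untreated cells, 26670000 ± 1993000 at 1 h, 28580000 ± 1971000 at 2 h and 27560000 ± 3401000 at 4 h (mean ± SD, n = 3 clones each). Of the symbols, 14185 had enough counts to be tested, and these held 99.9662% of all counts. In a principal component analysis of the 1000 most variable genes, the first component carried 69.5% of the variance. It ran from −29.9, −28.3 and −28.6 in the untreated libraries of clones a, b and c to 15.7, 54.3 and 39.2 at 4 h, so that clone a at 4 h lay below clone b at 2 h (21.9).

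Counts assigned to Esr1, the oestrogen receptor gene, were 9.44, 93.4 and 38.8 CPM in untreated clones a, b and c and 18.2, 260 and 39.1 CPM at 4 h. By edgeR the adjusted p for Esr1 was 0.842 at 1 h, 0.604 at 2 h and 0.486 at 4 h, and with clone as a block it was 0.069, 0.0207 and 0.00868. Whether these counts came from the construct or the endogenous gene was not determined. The 39 measured genes of the immediate-early and ERK feedback lists changed on average by 0.95, 1.46 and 1.20 on the log2 scale in clones a, b and c at 1 h, and by 1.25, 2.16 and 1.72 at 4 h.

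**Figure D1:**
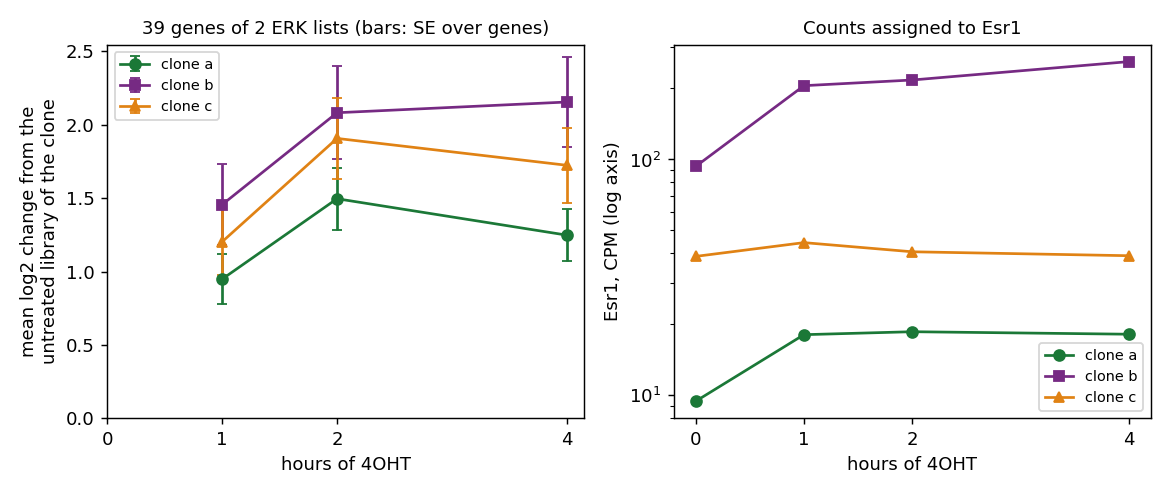
Left, mean log2 change (± SE over genes) of the 39 genes of the immediate-early and ERK feedback lists from the untreated library of each clone, against hours of 4OHT; right, counts assigned to Esr1 (CPM, log axis) in the same libraries. Clone b lies above clone c and clone c above clone a at each treated time in both panels.

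The comparison of 1 h with untreated cells asked which genes respond first when the construct is activated. The largest rise was in Egr1, an immediate-early zinc finger transcription factor, from 8.001 ± 1.81 to 294 ± 170 CPM (mean ± SD, n = 3). Its log2 change was 5.20 ± 0.67 (SE, edgeR adjusted p = 0.0157). Fos, a subunit of the AP-1 transcription factor, rose by 4.49 ± 0.53 on the log2 scale (edgeR adjusted p = 0.011), and Egr2, a relative of Egr1, by 4.75 ± 0.69 (edgeR adjusted p = 0.029). Among inhibitors that ERK induces against its own pathway, Spry4 rose from 49.6 ± 5.92 to 498 ± 217 CPM, Dusp6 from 52.9 ± 3.78 to 152 ± 16.9 CPM and Spry2 by 1.04 ± 0.14 on the log2 scale. Id3, an inhibitor of bHLH transcription factors, rose by 2.34 ± 0.28, Myc by 1.73 ± 0.26, Ier2 by 1.59 ± 0.18 and Tpt1 by 1.00 ± 0.13. Tpt1 has processed pseudogenes that can share its reads. The pluripotency genes Nanog (0.16 ± 0.13, adjusted p = 0.693), Klf4 (0.23 ± 0.24, adjusted p = 0.77), Esrrb (0.11 ± 0.13, adjusted p = 0.82), Tbx3 (−0.06 ± 0.21, adjusted p = 0.959), Sox2 (0.13 ± 0.13, adjusted p = 0.777) and Pou5f1 (0.35 ± 0.10, adjusted p = 0.29, or 0.014 with clone as a block) were not past the threshold. Etv4, an ETS factor downstream of ERK, was at 0.48 ± 0.21 (adjusted p = 0.416, or 0.00497 with clone as a block). The primitive endoderm factors were not past it either, with Gata6 at −0.20 ± 0.72 (adjusted p = 0.959) and Gata4 at −0.10 ± 0.40 (adjusted p = 0.964).

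Past the threshold at 1 h were 11 genes, all higher, of which 9 changed at least 2-fold. The gene outside the naming rule was Nlrp12 (0.73 ± 0.09, edgeR adjusted p = 0.0157), named after its value was seen, and its exons overlap a cluster of microRNA genes on the other strand. By edgeR 0 genes fell, against 31 in DESeq2 and 0 in limma-voom, and 1630 genes in either direction had an unadjusted p under 0.05. With clone as a block, 768 genes rose and 224 fell, 57 and 32 of them at least 2-fold, the same 11 among those that rose. DESeq2 gave 133 changed genes, limma-voom 6, a test against a 1.5-fold change 4 and a fit of the 2 groups alone 25. The count was 0 without the untreated library of clone a or of clone c or the 1 h library of clone c, with 1030, 1856 and 1059 genes at an unadjusted p under 0.05, so each call named here rests on each of these libraries. It was 1 without the 1 h library of clone b and 3 without the untreated library of clone b. Without all libraries of clone a, b or c it was 26, 0 and 0.

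Of 21 measured immediate-early genes, 5 rose at 1 h (Egr1, Egr2, Fos, Ier2 and Myc), 13 adjusted over the list alone and 15 with clone as a block. The list as a whole was higher (camera adjusted p = 2.77e-31, and adjusted p = 0.0385 with an estimated correlation). Of 18 ERK feedback genes 3 rose (Dusp6, Spry2 and Spry4), 6 adjusted over the list alone and 6 with clone as a block, and the list was higher (camera adjusted p = 1.44e-11, and 0.0273 with an estimated correlation). In the other lists 0 members passed in edgeR at 1 h. Adjusted over the list alone, 7 of 14 p53 target genes were higher, among them Plk2 (0.80 ± 0.17) and Sesn2 (0.56 ± 0.12), and 1 of 15 general pluripotency genes, Dppa2 (0.40 ± 0.09). With clone as a block 4 and 3 members of those lists were higher. Both lists were higher by camera (adjusted p = 2.49e-06 and 2.65e-04), each also with an estimated correlation (adjusted p = 0.0273 for both).

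Further lists were higher at 1 h by camera only with the preset correlation of 0.01. These were ribosome biogenesis (adjusted p = 2.18e-05, and adjusted p = 0.208 with an estimated correlation), with 8 of 24 members higher adjusted over the list alone and 9 with clone as a block, for example Fbl at 0.50 ± 0.10. Sterol synthesis (5.3e-06, and adjusted p = 0.142 with an estimated correlation) had 2 of 16 members higher over the list alone and 4 blocked. SRF and cytoskeleton genes (3.64e-05, and adjusted p = 0.139 with an estimated correlation) had 3 of 14 and 7 blocked. LIF and STAT3 targets (2.78e-04, and adjusted p = 0.139) had 2 of 15 and 5 blocked. Junb was at 2.67 ± 0.55. Cell cycle genes (5.5e-04, and adjusted p = 0.311 with an estimated correlation) had 0 of 23 over the list alone and 7 blocked. Ligands and receptors (0.00301, and adjusted p = 0.104) had 0 of 15 and 4 blocked. ETS-type ERK targets (0.00485, and adjusted p = 0.142 with an estimated correlation) had 3 of 20 and 7 blocked, such as Epha2 at 1.66 ± 0.28. Naive pluripotency genes (0.0278, and adjusted p = 0.167 with an estimated correlation) had 1 of 20 and 4 blocked. Primitive streak and mesoderm genes (0.0233, and adjusted p = 0.121 with an estimated correlation) had 0 of 11 and 2 blocked, and heat shock genes (0.0298, and adjusted p = 0.422) 0 of 12 and 2 blocked. The RNA quality list, of which 4 histone genes were measured, had 2 of 4 and 1 blocked (3.04e-04, and adjusted p = 0.142). Lists not past the threshold were the integrated stress response (camera adjusted p = 0.0512, 2 of 17 over the list alone and 3 blocked) and formative epiblast (0.176, 0 of 15 and 3 blocked). Also not past it were feeder fibroblast (0.202), neural (0.348), Wnt targets (0.348), primitive endoderm (0.725), trophoblast (0.838) and oestrogen response (0.99), the last 6 with 0 members over the list alone or blocked. Leaving out all libraries of a clone ended camera calls for the RNA quality list (clone a), heat shock (clone b or c), naive pluripotency (clone c) and primitive streak (clone c, adjusted p = 0.0512). The integrated stress list passed without clone a (adjusted p = 0.0259). By fry, which asks whether members move one way and compares them with no other genes, 9 of these lists missed the threshold.

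**Figure D2:**
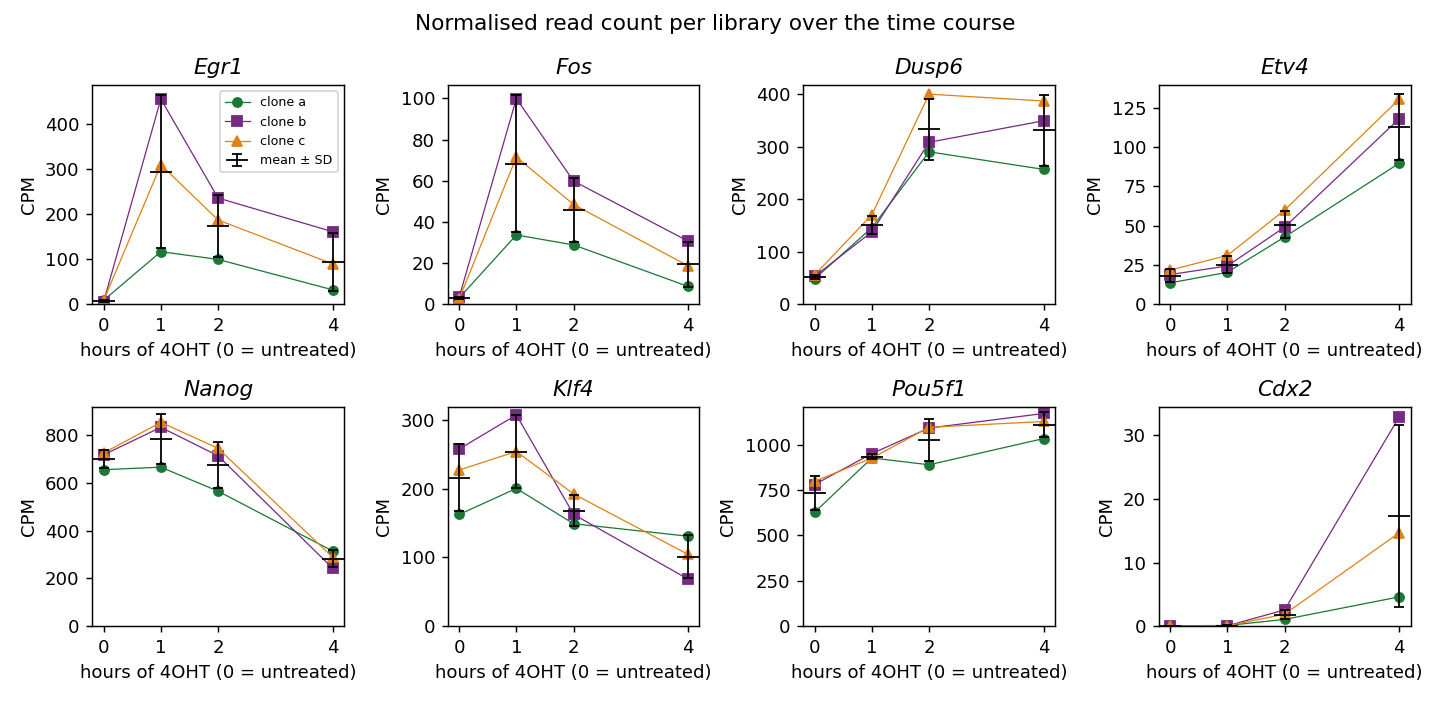
Normalised read count (CPM, linear axes from 0) of 8 genes against hours of 4OHT, with 1 line per clone and black bars for the mean ± SD of the 3 clones. Egr1 and Fos were highest at 1 h on average (294 and 68.4 CPM), Cdx2 rose from 0.0321 CPM in untreated cells to 17.4 CPM at 4 h, and Nanog fell to 282 CPM at 4 h.

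The comparison of 2 h with untreated cells asked how far the response had spread. Chemokine gene Ccl20 had 0 counts in the 3 untreated libraries and 450 at 2 h (5.28 ± 3.40 CPM), at least 155-fold higher against a floor of 3 counts over the untreated group. Egr3 rose by 7.96 ± 1.14 on the log2 scale (edgeR adjusted p = 0.00389), Jun, an AP-1 subunit, by 4.86 ± 1.05, Phlda1 by 5.08 ± 0.81 and Rrad, a small GTPase, by 5.17 ± 0.78. Cdx2, a homeobox factor of trophoblast and posterior embryo, went from 3 counts over the untreated libraries to 156, a ratio of 53.9 with a 95% counting interval of 18.1 to 264. The natriuretic peptide gene Nppb (5.78 ± 1.49), Lor (5.80 ± 1.12), Cyth4 (5.73 ± 0.96) and the forkhead gene Foxe1 (4.89 ± 1.29) completed the 10 largest rises. The largest falls were in Nlrp9c (−2.67 ± 0.43), Rgma, a BMP co-receptor (−2.64 ± 0.26), Gpr139 (−2.58 ± 0.72), the chemokine receptor gene Ackr3 (−2.47 ± 0.34), Kcnk3 (−2.10 ± 0.56), Plpp3 (−2.05 ± 0.31), Foxi3 (−2.02 ± 0.44), Cerkl (−1.88 ± 0.34), Dhrs3, a retinal reductase (−1.86 ± 0.29), and Cdc42ep2 (−1.85 ± 0.34). Floors and counting intervals cover counting error only. The exons of Jun, Phlda1, Rrad, Foxe1, Rgma, Kcnk3 and Cerkl overlap other annotated genes, and their values are uncertain to that extent.

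Of the fixed panel, Egr1 (4.44 ± 0.65), Fos (3.91 ± 0.52), Spry4 (4.08 ± 0.48), Dusp6 (2.65 ± 0.17, edgeR adjusted p = 4.9e-05) and Etv4 (1.48 ± 0.21) were higher at 2 h. Pou5f1 rose by 0.48 ± 0.10 (edgeR adjusted p = 0.0165) and Tbx3 fell by 0.92 on the log2 scale (SE 0.21, edgeR adjusted p = 0.0183). Both share exon sequence with antisense transcripts. Not past the threshold were Nanog (−0.05 ± 0.13, adjusted p = 0.803), Klf4 (−0.36 ± 0.24, adjusted p = 0.3), Esrrb (0.00 ± 0.13, adjusted p = 0.991), Sox2 (0.08 ± 0.13, adjusted p = 0.674), Gata6 (−0.47 ± 0.73, adjusted p = 0.679) and Gata4 (−0.34 ± 0.40, adjusted p = 0.576).

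In all, 1356 genes were higher and 942 lower at 2 h, 16.2% of those tested, and 300 and 281 of them changed at least 2-fold. With clone as a block 2924 were higher and 2830 lower, with 375 and 476 at 2-fold. Member counts of the lists are to be read beside these shares. A test against a 1.5-fold change left 81 genes and a fit of the 2 groups alone 1499. The count was 1048, 622 and 1282 without the untreated library of clone a, b or c, 379 and 338 without the 2 h library of clone b or c, and 97 and 1 without all libraries of clone b or of clone c. The calls of Nppb, Foxe1, Gpr139 and Kcnk3 were lost without any 1 of those 5 libraries, and limma-voom also lost Nppb and Foxe1. Jun lost its call without the untreated library of clone a or b or the 2 h library of clone b, and Tbx3 without the untreated library of clone b or c or the 2 h library of clone b. Foxi3 lost it without either library of clone b or the 2 h library of clone c, and Pou5f1 without the 2 h library of clone b or c.

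Of 21 immediate-early genes 17 were higher at 2 h and 0 lower, 19 adjusted over the list alone. Myc rose by 2.30 ± 0.27, Ier2 by 1.26 ± 0.18 and Arc by 4.34 ± 0.74 (camera adjusted p = 4.46e-21 for the list, and adjusted p = 0.143 with an estimated correlation). Of 18 ERK feedback genes 12 were higher, led by Dusp6, Spry2 (1.43 ± 0.14), the nuclear phosphatase gene Dusp4 (2.83 ± 0.28) and Spred1 (1.00 ± 0.11), and 0 lower. Adjusted over the list alone 13 were higher and 3 lower, and with clone as a block 14 and 3. That list was higher by camera (adjusted p = 4.09e-17, and 0.0121 with an estimated correlation). ETS-type ERK targets had 8 of 20 members higher, with Epha2 at 2.13 ± 0.29 and Etv4 among them, and 0 lower. Over the list alone 8 were higher and 1 lower, and blocked 9 and 3 (camera adjusted p = 5.25e-04, and adjusted p = 0.17 with an estimated correlation).

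Pluripotency genes moved in both directions at 2 h. Of 20 naive pluripotency genes, Nr0b1 (0.66 ± 0.09), Gbx2 (1.32 ± 0.26), Klf5 (0.80 ± 0.16) and Zfp42 (0.74 ± 0.17) rose, while Prdm14 (−1.40 ± 0.34), Tbx3 and Fgf4 (−0.78 ± 0.15) fell. Adjusted over the list alone 5 were higher and 4 lower, and with clone as a block 8 and 6. The list had a median of −0.05 and a mean of −0.02, and camera placed it up relative to other genes (adjusted p = 0.655). Of 15 general pluripotency genes 5 rose, 6 over the list alone and 9 with clone as a block, among them Dppa2 (0.67 ± 0.09) and Dppa4 (0.57 ± 0.10). That list was higher (camera adjusted p = 3.25e-04, and 0.0346 with an estimated correlation). Of 15 formative epiblast genes 4 rose, 4 over the list alone, namely Zic2 (1.47 ± 0.29), Pou3f1 (2.02 ± 0.40), Sox4 (1.01 ± 0.21) and the DNA methyltransferase gene Dnmt3a (0.64 ± 0.20). Blocked, 6 rose and 1 fell (camera adjusted p = 0.0459, adjusted p = 0.288 with an estimated correlation, and 0.0515 with RLE size factors). The calls of Gbx2 and Fgf4 were lost without the 2 h library of clone c, those of Zic2 and Pou3f1 without that of clone b, those of Klf5 and Sox4 without either, and that of Dnmt3a without any library but the untreated one of clone a. Exons of Gbx2, Pou3f1, Sox4 and Dnmt3a overlap other transcripts.

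Lists of growth genes were higher at 2 h with the preset correlation. Of 24 ribosome biogenesis genes 16 rose, 20 over the list alone, for example Nop16 (0.38 ± 0.05) and Nop2 (0.46 ± 0.08) (camera adjusted p = 5.13e-09, and adjusted p = 0.17 with an estimated correlation). Of 16 sterol synthesis genes 10 rose, 12 over the list alone, with Insig1 at 0.95 ± 0.15 and Cyp51 at 0.92 ± 0.16 (camera adjusted p = 4.72e-08, and adjusted p = 0.17 with an estimated correlation). Of 23 cell cycle genes 10 rose, 12 over the list alone, with Aurka at 0.63 ± 0.13, whose call was lost without the 2 h library of clone b or c. That list was higher (camera adjusted p = 6.06e-05, and adjusted p = 0.288 with an estimated correlation). The integrated stress list had 4 of 17 higher, 4 over the list alone and 6 blocked, with Atf4 at 0.61 ± 0.07 (0.00215, and adjusted p = 0.208). Heat shock genes had 3 of 12, 3 over the list alone and 6 blocked (0.01, and adjusted p = 0.355). SRF and cytoskeleton genes had 4 of 14 higher, 4 over the list alone and 8 blocked, with Srf at 0.73 ± 0.13 (0.00864, and adjusted p = 0.288). LIF and STAT3 targets had 6 of 15 higher and 1 lower, also over the list alone, and blocked 6 and 3, with Pim1 at 1.41 ± 0.22 (0.0223, and adjusted p = 0.288). Primitive streak and mesoderm genes had 1 of 11 higher, Evx1 (2.56 ± 0.40), 2 over the list alone, and blocked 5 higher and 1 lower (0.0485, adjusted p = 0.17 with an estimated correlation and 0.061 with clone as a block). The histone genes of the RNA quality list had 1 of 4 higher, 2 over the list alone and 2 blocked (0.0485, adjusted p = 0.355 with an estimated correlation and 0.14 with clone as a block). The last pair of calls was also lost with RLE size factors (0.0557 and 0.0552), with the Lars2 group of genes left out (0.0509 for both) and without clone a (0.202 and 0.0611), and that of the streak list without clone c (0.0554).

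Lists not past the threshold at 2 h were ligands and receptors (camera adjusted p = 0.12, or 0.00299 with clone as a block), p53 targets (0.0919), Wnt targets (0.199), trophoblast (0.425), feeder fibroblast (0.62), oestrogen response (0.62), neural (0.64) and primitive endoderm (0.655). Hbegf (3.09 ± 0.51) and Bmp4 (2.40 ± 0.41) were among 4 of 15 ligands and receptors that rose while Fgf4 fell, against 6 and 2 over the list alone and 6 and 3 blocked. Of 14 p53 targets 4 rose, such as Sesn2 (0.70 ± 0.12), and 1 fell, Zmat3 (−0.44 ± 0.11), against 5 and 1 over the list alone and 5 and 2 blocked. Of 14 Wnt targets Cdx2 and Tcf7 (0.74 ± 0.17) rose, also over the list alone, and blocked 4 rose and 1 fell. Of 10 trophoblast genes Cdx2 rose and Ascl2 fell (−2.01 ± 0.53), also over the list alone, and blocked 3 rose and 2 fell. Of 9 oestrogen response genes 1 fell, Myb (−1.61 ± 0.35), against 1 higher and 3 lower over the list alone and 3 and 3 blocked. Their median was 0.10, their mean −0.10 and the camera direction down. The primitive endoderm, neural and feeder lists had 0 of 22, 5 and 5 members past the threshold, also over the list alone, and blocked 4 higher and 3 lower, 1 lower, and 1 higher. At 1 h the oestrogen list had a median of 0.00, a mean of 0.04 and a camera direction of down. The calls of Zmat3 and Ascl2 were lost without any 1 of 5 libraries, that of Tcf7 without the untreated library of clone b or the 2 h library of clone b or c, and that of Myb without either of those 2 h libraries.

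At 4 h the question was which genes follow over the longer exposure. Ccl20 reached 4113 counts (48.6 ± 45.6 CPM), at least 1466-fold higher against the same floor. Cdx2 reached 1459 counts (17.4 ± 14.3 CPM), a ratio of 520 with a 95% counting interval of 178 to 2525. Egr3 rose by 7.83 ± 1.14 on the log2 scale (edgeR adjusted p = 7.22e-04), Nppb by 7.32 ± 1.52, Cyth4 by 6.43 ± 0.96 and Foxe1 by 5.99 ± 1.22. Ankrd63 (5.93 ± 0.90), Phlda1 (5.83 ± 0.81), Vgf, a neuropeptide precursor gene (5.62 ± 0.75), and Npy, encoding neuropeptide Y (5.50 ± 0.62), were the others of the 10 largest rises. The largest falls were in Gnat3, a taste transducin subunit (−3.30 ± 0.58), Sh2d4a (−3.20 ± 0.42), Rnf144b (−2.90 ± 0.51), Rasgef1a (−2.81 ± 0.24), the ETS-family gene Spic (−2.59 ± 0.27), Acot3 (−2.55 ± 0.46), Trim47 (−2.54 ± 0.49), Rnf152 (−2.52 ± 0.63), Gpr139 (−2.49 ± 0.72) and Rassf4 (−2.46 ± 0.25). Rasgef1a, Acot3, Trim47, Rnf152, Foxe1 and Phlda1 have exons that overlap other annotated genes.

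Nanog, the core naive pluripotency factor, fell at 4 h from 699 ± 38.4 to 282 ± 36.3 CPM (mean ± SD, n = 3), a log2 change of −1.31 ± 0.13 (SE, edgeR adjusted p = 1.26e-04). Klf4 fell from 216 ± 48.5 to 101 ± 31.3 CPM (edgeR adjusted p = 0.00571) and Tbx3 from 145 ± 27.9 to 74.1 ± 16.4 CPM (edgeR adjusted p = 0.00523). Pou5f1, which encodes OCT4, rose from 735 ± 93.9 to 1110 ± 70.8 CPM (edgeR adjusted p = 0.00189). Dusp6 (2.65 ± 0.17), Spry4 (3.58 ± 0.47), Etv4 (2.63 ± 0.22), Egr1 (3.56 ± 0.63) and Fos (2.67 ± 0.50) were higher. Not past the threshold were Esrrb (−0.27 ± 0.13, adjusted p = 0.132), Sox2 (0.17 ± 0.13, adjusted p = 0.325), Gata6 (0.13 ± 0.70, adjusted p = 0.908) and Gata4 (−0.62 ± 0.41, adjusted p = 0.262, or 0.0421 with clone as a block). In GENCODE M21 (GRCm38, the assembly also called mm10), Nanog lies on chromosome 6 at 122707489 to 122714633, Klf4 on chromosome 4 at 55527143 to 55532466, Egr1 on chromosome 18 at 34859823 to 34864984, Cdx2 on chromosome 5 at 147300805 to 147307270 and Ccl20 on chromosome 1 at 83116766 to 83119167.

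At 4 h 2551 genes were higher and 2140 lower, 33.1% of those tested, and 908 and 598 of them changed at least 2-fold. With clone as a block 3722 were higher and 3652 lower, with 954 and 729 at 2-fold. A test against a 1.5-fold change left 909 genes. The count was 3043 and 3053 without the 4 h library of clone b or c, and 1913 and 919 without all libraries of clone b or of clone c. Of the genes named as largest or in the panel, Gpr139 lost its call without the untreated or 4 h library of clone c or the 4 h library of clone b, and Nppb lost it with limma-voom. Without all libraries of clone c, Egr1, Fos, Klf4, Pou5f1, Foxe1, Nppb, Acot3, Trim47, Rnf152 and Gpr139 lost their calls, and without all of clone b Klf4 and Gpr139.

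**Figure D3:**
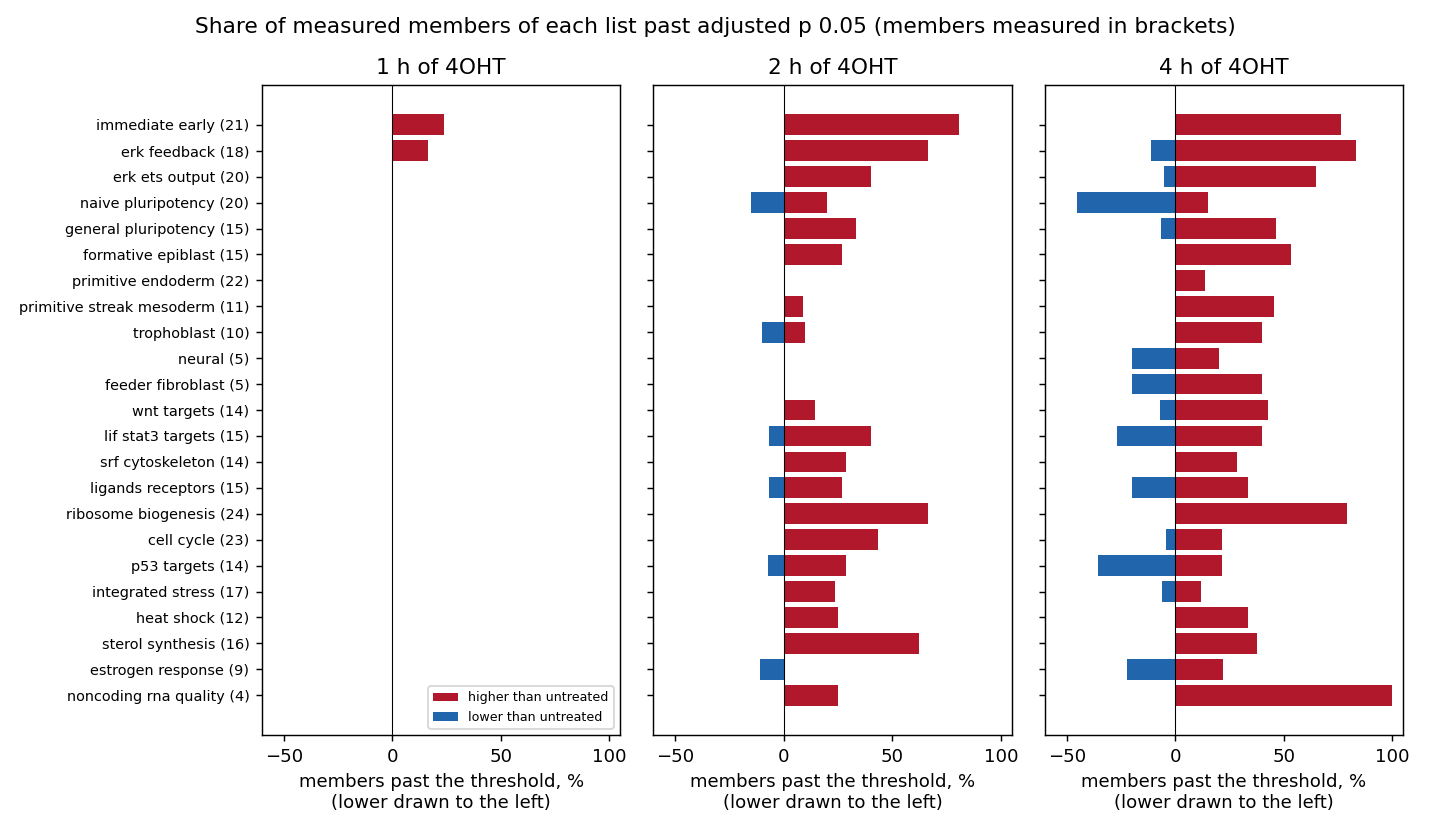
Share of the measured members of each fixed list (% of members, number measured in brackets) past an adjusted p of 0.05 in edgeR at 1, 2 and 4 h against untreated, higher members drawn to the right and lower ones to the left. The ERK feedback list went from 3 of 18 members higher at 1 h to 15 at 4 h, and the naive pluripotency list had 9 of 20 members lower at 4 h. Among all 14185 genes tested, 0.0776%, 16.2% and 33.1% were past the threshold in either direction at 1, 2 and 4 h.

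Of 20 naive pluripotency genes 9 fell at 4 h, also over the list alone. Besides Nanog, Klf4 and Tbx3 these were Prdm14 (−2.06 ± 0.35), Fgf4 (−1.39 ± 0.16), Fbxo15 (−1.06 ± 0.11), Tfcp2l1 (−0.96 ± 0.32), Tcl1 (−0.64 ± 0.15) and Jam2 (−0.64 ± 0.20). Gbx2 (2.67 ± 0.27), Nr0b1 (1.25 ± 0.09) and Klf5 (0.99 ± 0.17) rose, 5 members rose over the list alone, and with clone as a block 11 fell and 6 rose. The list as a whole was not past the threshold (camera adjusted p = 0.11, or 0.0375 without clone b). Fry, which asks whether members move one way and compares them with no other genes, placed it lower (adjusted p = 0.00882). Of 15 general pluripotency genes 7 rose, also over the list alone, among them Utf1 (1.60 ± 0.23) and Dppa4 (0.84 ± 0.10), and Tdgf1 fell (−0.37 ± 0.09). Under the block 9 were higher and 2 lower (camera adjusted p = 0.00139, and adjusted p = 0.0596 with an estimated correlation). Of 15 formative epiblast genes 8 rose, also over the list alone, led by Pou3f1 (3.27 ± 0.41), Sox4 (1.84 ± 0.22) and Dnmt3a (1.37 ± 0.20), and blocked 9 rose and 2 fell. The list was higher (camera adjusted p = 0.00816, adjusted p = 0.222 with an estimated correlation, and 0.0564 without clone a). LIF and STAT3 targets had 6 of 15 higher, such as Junb (3.40 ± 0.57) and Pim1 (1.37 ± 0.22), and 4 lower, Klf4, Tfcp2l1, Lifr (−0.46 ± 0.11) and Spp1 (−0.38 ± 0.06). The counts were 7 and 4 both over the list alone and blocked (camera adjusted p = 0.127, or 0.0144 with clone as a block).

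Of 21 immediate-early genes 16 were higher at 4 h, 18 over the list alone, with Ier5 at 2.25 ± 0.23 and Myc at 2.41 ± 0.27, and blocked 19 were higher and 1 lower. The list was higher (camera adjusted p = 9.01e-10, and adjusted p = 0.234 with an estimated correlation). Of 18 ERK feedback genes 15 were higher, with Dusp4 at 4.21 ± 0.29 and Spred1 at 1.64 ± 0.11, and 2 lower, Lrig3 (−1.20 ± 0.23) and Lrig1 (−0.50 ± 0.17), which encode inhibitors of receptor tyrosine kinases. The counts over the list alone were 15 and 2 (camera adjusted p = 3.04e-14, and 0.0311 with an estimated correlation). ETS-type ERK targets had 13 of 20 higher, such as Trib1 (1.98 ± 0.24) and Rapgef5 (1.21 ± 0.14), and 1 lower, the ephrin receptor gene Epha4 (−0.76 ± 0.18). Over the list alone the counts were 13 and 2, and blocked 13 and 3 (camera adjusted p = 6.57e-06, and adjusted p = 0.102 with an estimated correlation). Of 24 ribosome biogenesis genes 19 were higher, 22 over the list alone, with Rrp9 at 1.08 ± 0.17 (camera adjusted p = 1.85e-07, and adjusted p = 0.222 with an estimated correlation). Sterol synthesis had 6 of 16 higher, also over the list alone, and 12 blocked (0.00541, and adjusted p = 0.403). The 4 measured histone genes of the RNA quality list were all higher in edgeR, from 0.73 ± 0.20 for Hist1h1c to 1.52 ± 0.27 for Hist1h4d, also over the list alone (camera adjusted p = 4.29e-04, and adjusted p = 0.222 with an estimated correlation).

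Markers of other lineages were also measured at 4 h. For comparison, 2551 of all 14185 genes tested were higher at this time and 2140 lower, and blocked 3722 and 3652. Of 11 primitive streak and mesoderm genes 5 rose, Eomes (2.34 ± 0.22), Evx1 (3.71 ± 0.41), T or Brachyury (2.20 ± 0.39), the VEGF receptor gene Kdr (1.72 ± 0.39) and Mesp2 (1.09 ± 0.38). Over the list alone 6 were higher and 2 lower, and blocked 6 and 3 (camera adjusted p = 0.038, adjusted p = 0.195 with an estimated correlation, 0.0889 with clone as a block and 0.223 without clone a). Of 10 trophoblast genes Cdx2, Tead4 (1.91 ± 0.28), Krt18 (1.92 ± 0.44) and Gata3 (1.32 ± 0.45) rose, also 4 over the list alone, and blocked 7 rose and 1 fell. Of 14 Wnt targets 6 rose, such as Sp5 (2.79 ± 0.42) and Tcf7 (1.26 ± 0.17), and Apcdd1 fell (−0.49 ± 0.15), also over the list alone, and blocked 6 rose and 2 fell. The last pair of lists had a camera adjusted p of 0.04995 each, which became an adjusted p of 0.331 and 0.234 with an estimated correlation and 0.0547 for both with RLE size factors. Without clone a they were 0.0762 and 0.179, and the Wnt list was 0.0577 without clone c. Of 22 primitive endoderm genes Lamb1 (0.76 ± 0.14), Bmp2 (1.43 ± 0.37) and Lrp2 (0.84 ± 0.29) rose, 2 over the list alone, and blocked 7 rose and 3 fell (camera adjusted p = 0.443). In edgeR that is a smaller share of the list than the 33.1% past the threshold among all genes tested. Of 5 neural genes Nes rose (1.33 ± 0.25) and Sox1 fell (−1.87 ± 0.42), 2 and 2 over the list alone and blocked. The list had a median of −0.03, a mean of 0.01 and a camera direction of down (adjusted p = 0.972). Of 5 feeder fibroblast genes Thy1 (2.31 ± 0.31) and Col1a1 (1.28 ± 0.44) rose and Pdgfrb (−0.96 ± 0.29) fell, also over the list alone, and blocked 2 rose and 2 fell (camera adjusted p = 0.443). Gata3, Pdgfrb and Col1a1 lost their calls without several single libraries, Bmp2 without the untreated library of clone a or the 4 h library of clone b or c, and Lrp2 without any but the untreated library of clone a. None of the two-cell-like genes was measured well enough to be tested.

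The remaining lists were not past the threshold at 4 h. Of 15 ligands and receptors 5 rose, with Bmp4 at 2.97 ± 0.42 and Hbegf at 2.78 ± 0.50, and 3 fell, Fgf4, Lif (−0.98 ± 0.27) and Fgfr1 (−0.82 ± 0.15). The counts were 7 and 3 both over the list alone and blocked (camera adjusted p = 0.666). Of 23 cell cycle genes 5 rose, with the cyclin D2 gene Ccnd2 at 2.64 ± 0.32, and the inhibitor gene Cdkn1a fell (−0.76 ± 0.19), also over the list alone, and blocked 11 rose and 4 fell (0.145). Of 14 p53 targets 3 rose, Pmaip1 at 2.47 ± 0.29 among them, and 5 fell, such as Ccng1 (−0.71 ± 0.11) and Trp53inp1 (−1.22 ± 0.20), also over the list alone, and blocked 3 and 6. The median was −0.10, the mean 0.02 and the camera direction down (0.431). SRF and cytoskeleton genes had 4 of 14 higher, also over the list alone, with Zyx at 1.43 ± 0.30, and blocked 6 higher and 2 lower (0.215). Heat shock genes had 4 of 12 higher, also over the list alone, and 5 blocked, with Hsph1 at 0.58 ± 0.12 (0.163). The integrated stress list had 2 of 17 higher, Xbp1 (0.94 ± 0.21) and Atf4 (0.33 ± 0.07), and Hspa5 lower (−0.33 ± 0.07), also over the list alone, and 4 and 1 blocked (0.666). Of 9 oestrogen response genes Greb1 (0.93 ± 0.29) and Ctsd (0.32 ± 0.11) rose and Myb (−1.48 ± 0.34) and Pgr (−1.10 ± 0.36) fell, 3 and 2 over the list alone and 5 and 2 blocked (0.892). Greb1, Ctsd and Pgr lost their calls without several single libraries. Exons of Bmp4, Ccnd2, Junb, Pim1, Cdkn1a, Fgfr1, Zyx, Evx1, Eomes, Gata3, Rrp9, Greb1, Ctsd and Myb overlap other annotated genes.

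Between treated times, which share no untreated library, the direct comparisons asked which responses went on. From 1 h to 2 h, Sox8 (4.00 ± 0.45, edgeR adjusted p = 0.0237), the heparan sulfate enzyme gene Hs3st3b1 (2.48 ± 0.31), Pcdh1 (1.94 ± 0.27), Dusp4 (1.83 ± 0.27) and Fjx1 (1.71 ± 0.24) rose and Amotl2, a YAP regulator, fell (−0.67 ± 0.10, edgeR adjusted p = 0.0322). These were among 8 rises and 1 fall, against 1011 and 774 with clone as a block and 2291 genes at an unadjusted p under 0.05. The number of changed genes was 575 in DESeq2, 0 in limma-voom (2318 at an unadjusted p under 0.05), 43 with no low-count filter, 31 with a stricter one, 30 with the Lars2 group of genes left out, 1 in the test against a 1.5-fold change and 0 in a fit of the 2 groups (2497 at an unadjusted p under 0.05). It was 0 without any 1 of the 1 h libraries or the 2 h library of clone b or c, and 159 without the 2 h library of clone a, so each call was lost without any 1 of 5 of the 6 libraries.

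From 2 h to 4 h the largest rise under the naming rule was in Cyp26a1, which encodes a retinoic acid hydroxylase. It went from 0.313 ± 0.0764 to 7.08 ± 4.03 CPM (edgeR adjusted p = 0.0033), and Aldh1a3, a retinaldehyde dehydrogenase gene, rose by 3.38 ± 0.52 on the log2 scale. Cdx2 (3.23 ± 0.58), Ccl20 (3.20 ± 0.73) and St8sia4 (3.01 ± 0.53) followed. Nanog fell between these times (−1.25 ± 0.13, edgeR adjusted p = 0.0033), as did Rab44 (−1.74 ± 0.33), Olfr985 (−1.45 ± 0.26), Cpt1a (−1.19 ± 0.22) and Rassf4 (−1.19 ± 0.25). In all 464 genes rose and 200 fell, and with clone as a block 1700 and 1415. The count was 1395 in DESeq2, 26 in the test against a 1.5-fold change and 0 in a fit of the 2 groups (2320 genes at an unadjusted p under 0.05). Without the 2 h library of clone b or c it was 140 and 129, without the 4 h library of clone a, b or c 1468, 199 and 127, and without all libraries of clone b or of clone c 0. Cdx2 and St8sia4 lost their calls without the 2 h library of clone c, and Cpt1a without either library of clone c. Rab44 and Olfr985 lost them without either library of clone b or of clone c, and Ccl20 and Rassf4 without any 1 of the libraries other than the 4 h library of clone a.

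From 1 h to 4 h 1535 genes rose and 1240 fell, against 2839 and 2802 with clone as a block. Ccl20 (7.79 ± 1.03), Cdx2 (edgeR adjusted p = 4.24e-04), Nppb (5.86 ± 1.36) and Cyth4 (5.56 ± 0.89) rose the most with Foxe1, which went from 1 count to 271, a ratio of 265 with a 95% counting interval of 47.2 to 10520. Gnat3 (−2.98 ± 0.59), Sh2d4a (−2.83 ± 0.42), Trim47 (−2.47 ± 0.49), Rnf144b (−2.46 ± 0.52) and Rasgef1a (−2.36 ± 0.24) fell the most. The test against a 1.5-fold change left 551 genes, and the count was 1793 and 1724 without the 1 h library of clone b or c and 1604 and 1528 without the 4 h library of clone b or c. It was 795 and 50 without all libraries of clone b or of clone c, and Nppb lost its call without the 1 h library of clone a.

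In a single test of the whole time course, 3886 genes differed at some time, and 8054 with clone as a block. The count was 2134 without the 4 h library of clone c, 675 without all libraries of clone b and 27 without all of clone c. The p-values measure the spread between 3 clones of 1 cell line.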

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

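The tests of construct RNA, the 3 tests of the genes varying with Lars2, the test of transcription time and the span values without the untreated library of clone a were chosen only after the result was seen. A single gene, 1600014C10Rik, was past the threshold in opposite directions at 2 times. It was lower at 2 h (log2 change −0.86, edgeR adjusted p = 0.0378) and higher at 4 h (0.70, adjusted p = 0.0414), and the direct comparison of 4 h with 2 h gave a difference of 1.555 (adjusted p = 0.00856).

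The immediate-early and ERK feedback lists (39 genes) changed more in clone b than in clone a, and the gap of the mean log2 change of b over a at 4 h was 0.91 (SE over genes 0.17), in the same direction for 31 of 39 genes. The gap was 0.906 after all libraries were thinned to 24210000 counts, but this decides little about depth. Library totals ran only from 24213641 to 31435301, and thinning leaves the expected CPM as it was, so the gap could hardly move. A scaling error was argued against, since the gap of the naive pluripotency list was −0.338 (SE 0.15). A higher start in clone a was also argued against, because its untreated level was below that of clone b by a difference of −0.1075 (SE 0.0698). A candidate explanation that stays open is more construct RNA in clone b: Esr1 counts put the clones in the order of the response, b, c, a, at 3 of 3 treated times, but with 3 clones an order has a permutation p of at least 0.167. With 1 library per clone and time, the difference between clones has no replicates of its own.

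A group of 15 genes (among them Lars2, Gphn, Kpna1, Cd44, Camk1d, Col6a6, Gm20594, Kcnip1, Sugct, Il31ra, Rsph3a, Fgfr2, Vwa3a and Tmtc2) varied together across libraries and took 0.266% to 7.03% of all counts, with Lars2 alone at 0.0822% to 2.71%. A shared source of reads stays open, because the ratio of a member to Lars2 varied by a median of 35.1% of the spread of Lars2 itself, between the limits set for and against it. Members differed in this. Gphn, Camk1d, Cd44 and Kpna1 (1827 to 6971 CPM) had an SD of the log2 ratio of 0.0736 to 0.185, against 1.704 for Lars2 itself. Fgfr2 (248 CPM) had 0.91 and Tmtc2 (8.03 CPM) 1.245. All were chosen by correlation with Lars2, so close tracking alone does not settle the source. Reads of mitochondrial 16S ribosomal RNA lie between the limits set for and against them. Of the 15 members 1, Gm20594, shares sequence with mt-Rnr2 (435 bases, 88.506% identical) in the transcripts searched. It averages 58.8 CPM, against 9909 CPM for Lars2. The other members, Lars2 among them, share 0 bases there, which argues against this source for them, while it stays open for Gm20594. Other ribosomal RNAs were not searched. A response to 4OHT may be involved and cannot be told apart from chance here. The spread between times had an exact permutation p of 0.201 with times permuted within clones and 0.133 by a permutation over all libraries, which was the deciding value until both had been seen. From untreated to 4 h the share of counts was lower in 3 of 3 clones and the mean log2 CPM in 2 of 3, with a range of group means of 2.23 on the log2 scale against ranges within groups of 0.96 to 3.06. Of the 15 genes, 1 was past the threshold at 2 or 4 h, and Cd44 and Fgfr2 are members of fixed lists.

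Shorter genes had higher log2 changes than longer ones. Across 14038 genes, which are not independent replicates, the rank correlation of the log2 change with genomic span was −0.18 at 1 h, −0.15 at 2 h and −0.14 at 4 h. Much of it rests on the untreated library of clone a: from log2 CPM means without that library it was −0.0672, −0.0829 and −0.0921. Clone a against its own untreated library gave −0.339, −0.278 and −0.293, clone b −0.00653, −0.0574 and −0.0521 and clone c −0.0826, −0.131 and −0.0999, and the untreated libraries of clones b and c differed from that of clone a by −0.256 and −0.26. Length-dependent yield of the libraries stays open, because pairs of libraries of 1 group had a median absolute correlation of 0.0722 (0.00805 to 0.26) against 0.0999 (0.00653 to 0.339) for treated against untreated libraries of 1 clone. A delay of long genes, which would put correlations between treated times above 0, also stays open. The correlation for the change from 1 h to 4 h, −0.0829, lies within the range of those same-group pairs. The bound of that test was first ±0.05, by which the value argued against a delay. It was widened to this range after the value was seen. The top of the range comes from pairs with the untreated library of clone a, which is not in that comparison. The 1 h libraries of clones a and b differed by 0.0874. The changes from 1 h to 2 h and from 2 h to 4 h gave −0.0569 and −0.0567, also below 0.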

How the results depend on the processing

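For gene counts, the settings that left out all libraries of a clone, left out the genes varying with Lars2 or combined DESeq2 with the clone block were chosen only after seeing the data. Counts of changed genes are given for 1, 2 and 4 h against untreated, 1 to 2 h, 2 to 4 h, 1 to 4 h and any time, 11, 2298, 4691, 9, 664, 2775 and 3886 as reported. RLE size factors kept each within 1.5 times, and no direction reversed in the values that each setting could test, 322 to 358 of the 358 for 200 named genes and all 69 list tests, a change of sign being counted only where a value was past the threshold in either fit. With clone as a replicate block the counts were 992, 5754, 7374, 1785, 3115, 5641 and 8054, 69 named gene values came past the threshold, 0 lost their call in edgeR, and 5 list calls changed. DESeq2 moved 1 h to 133, 1 to 2 h to 575 and 2 to 4 h to 1395, and with the clone block gave 1298, 5286, 2171, 3004, 5165 and 7693 for all but 4 h. limma-voom moved 1 h to 6 and 1 to 2 h to 0. The test against 1.5-fold gave 4, 81, 909, 1, 26 and 551, as that threshold asks more. Fitting only the 2 groups compared gave 25 at 1 h, 1499 at 2 h and 0 for 1 to 2 h and 2 to 4 h, with fewer libraries in the fit. For 1 to 2 h, no low-count filter gave 43, a stricter one 31 and leaving out the genes varying with Lars2 30. Leaving out a library or a clone gave 0 to 26 at 1 h, 1 to 3248 at 2 h, 919 to 5559 at 4 h, 0 to 299 for 1 to 2 h, 0 to 1468 for 2 to 4 h, 50 to 3803 for 1 to 4 h and 27 to 4686 for any time; the lowest came without clone b or c, and without single libraries for 1 h and 1 to 2 h. Of 69 list tests 40 passed, 7 with an estimated correlation, 34 by fry and 33 to 40 without a clone. All 40 were calls of higher and 0 of lower, in lists of unlike function. Without clone a 8 list calls were lost and 1 came past the threshold, and not all of the 8 are named above. These 69 tests are all against untreated. Between treated times, outside the plan, camera gave calls in both directions. From 2 h to 4 h naive pluripotency genes (adjusted p = 0.00183, or 0.192 with an estimated correlation) and p53 targets (0.00163, or 0.192) were lower. Trophoblast genes were higher (0.0104, or 0.251). Except where the construction is named, the cause was not tested. In simulated data at this depth, with 200 genes changed, the 4 h comparison recovered 37.3% of 1.5-fold changes with no clone effect. With a clone effect of the real size it recovered 41.8%, or 76.1% with the block, so small changes were missed there. The first setting already held the clone differences as noise, so 37.3% against 41.8% does not show what a clone effect costs. The real 4 h comparison called 4691 genes, far more than were changed in the simulation, so these shares cannot be carried over to it.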

Other observations

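The genes of opposite direction named here and the splits within clones were chosen only after the result was seen. With clone as a block, 33 genes were past the threshold in opposite directions at 2 h and at 4 h, 25 of them lower first and higher later. Nodal, a TGF-beta ligand gene of the early embryo, was higher at 2 h (log2 change 0.42, edgeR adjusted p = 0.00674 with the block) and lower at 4 h (−0.49, adjusted p = 0.00192), and the direct change from 2 h to 4 h was past the threshold without the block too (−0.93 ± 0.20, adjusted p = 0.0287). Trib2, a pseudokinase gene on the ETS-type list, went the other way (−1.31 at 2 h, adjusted p = 0.0213, and 1.37 at 4 h, adjusted p = 0.00595, both with the block), as did Rreb1, a RAS-responsive transcription factor gene (−0.60, adjusted p = 4.16e-04, and 0.21, adjusted p = 0.044). The kinase gene Cdk2 moved up and then down by small amounts (0.18, adjusted p = 0.0124, and −0.19, adjusted p = 0.00627). Between 1 h and 4 h the block gave 8 such genes, with the antiproliferative immediate-early gene Btg2 higher at 1 h (0.75, adjusted p = 0.0087) and lower at 4 h (−0.38, adjusted p = 0.025), and between 1 h and 2 h it gave 1.

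Other splits of the libraries into groups of the same sizes were run for each count. For the test of any time, 1 of 100 splits, the real one, gave as many genes (3886, against at most 958 in the others). Of these others only 3 kept the pairing by clone, so times were also permuted within clones, and it was again 1 of 100, against at most 1376. A share of 1 in 100 is the smallest that either set can give, so chance is made unlikely but is not excluded. Unlike the real one, the other splits put libraries of different times in 1 group. For each comparison of 3 against 3 libraries, 1 of 10 splits gave as many genes, and 10 splits are too few for a share under 0.05. The real counts were 11, 2298, 4691, 9, 664 and 2775 for 1, 2 and 4 h against untreated, 1 to 2 h, 2 to 4 h and 1 to 4 h, and the highest of the other splits was 0 in each, including the 3 that part all 3 clone pairs as the real one does. Unlike the real one, those 3 put libraries of both times on each side.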
